A study of Caenorhabditis elegans with 2 samples.

How the data were processed

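The series measured where ZAG-1, a zinc finger homeodomain transcription factor of the ZEB class, was bound in the genome of Caenorhabditis elegans larvae at the L1 stage. Chromatin immunoprecipitation and sequencing was done on whole animals that carried an integrated transgene for zag-1 fused to green fluorescent protein in a strain mutant for unc-119, per the labels. There were 2 biological replicates, both in 1 group, so no comparison between conditions was made. No control samples were used here, and the number of reads of either library is not given in the sources used here.

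The authors deposited 4 kinds of peak list on each of 2 genome builds, ce11 and ce10, which makes 8 lists. A list was called for each replicate and a further list on both replicates pooled, each against a control alignment, per the labels and the release notes that accompany them. These lists hold 30000 entries each and are named there as peaks and background, so most of their entries are not called as bound. The optimal list is named as peaks thresholded on the irreproducible discovery rate. That name does not show that each peak was found in both replicates. The aligner, the peak caller, their versions and that threshold are not given in the sources used here. All 8 files had the checksum that the release notes give.

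Each entry has a signal value, a −log10 q and a summit position as deposited by the authors. The signal value is the authors' own value for that peak, with a formula and scale that are not given in the sources used here, and it was used only to describe, rank or filter peaks within a list. The −log10 q values are those of the authors' peak caller and were used only as a description. Entries have a fixed width per list with the summit at the middle, except 3 pooled entries and 1 entry of replicate 2 that are narrower. A fixed width says nothing about the width of a bound region.

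Positions on ce11 were compared with the WBcel235 assembly, which is the same build, and with Ensembl release 115 gene models on chromosomes I to V and X. No coordinates were converted between builds, and the ce10 lists were used for counts, replicate agreement and shares per chromosome. A summit was placed in the TSS window when it lay within 500 bp of the annotated start of a protein-coding transcript, and otherwise in a coding exon, UTR, intron, other gene or intergenic sequence. A peak was assigned to the protein-coding gene with the nearest start, within 5000 bp of the summit. Of the 19973 protein-coding genes, 12582 were assigned 1 or more pooled entries.

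The optimal list was compared with the pooled list, whose entries are the regions that could have entered it. Location classes and gene lists were tested with 10000 draws of as many pooled entries, keeping the number per chromosome, and chromosomes with 10000 draws without that restriction. These tests were two-sided permutation tests, and the smallest p they can give is 2.00e-04. The overlap of the replicates was tested with a one-sided permutation test of 10000 draws, whose smallest p is 1.00e-04. Spearman's rho and the difference in median signal rank had two-sided permutation tests of 100000 resamples, whose smallest p is 1.00e-05. Motifs were counted on both strands within 100 bp of the summit and compared by Fisher's exact test, two-sided, with pooled entries that overlap no optimal peak. Benjamini-Hochberg adjustment was made over 6 classes, 6 chromosomes, 16 gene lists, 11 motifs or 2080 hexamers, and an adjusted p of 0.05 or less was taken as past the threshold. Shares have 95% Wilson intervals. Odds ratios have approximate 95% intervals on the log scale with 0.5 added to each cell. Intervals cover counting error only.

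Groups, tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The rule names zag-1 and unc-119, the genes of the 20 peaks with the highest signal in the optimal list with coordinates for the first 5, and for each gene list up to 4 members with the highest signal. The 16 lists covered neuron identity transcription factors, pan-neuronal synaptic and vesicle genes, neurotransmitter synthesis and transport, neuronal receptors and ion channels, neuropeptides, touch receptor neuron genes, axon guidance, cell junctions and polarity, pharynx, body wall muscle, intestine, epidermis and cuticle, germline, ribosomal proteins, the proteasome and histones. 5 list terms matched no annotated symbol and were left out. They were nca-1, efn-1, hum-9, opt-2 and elt-5.

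The alternatives were a stricter list of the upper 239 optimal peaks, other overlap rules, ce10 lists, other windows and assignments, random positions or GC-matched entries as background, and the lists of a single replicate in place of the optimal list. For the last, the 478 highest ranked entries of that replicate were compared with draws from its whole list. For motifs they were compared with the entries of that list that overlap none of them. Draws matched on GC content in bins of 5% and on the TSS window, motifs among TSS-window peaks, replicate pairs with entries that occur in no other pair, the removal of narrower peaks and the overlap with non-coding genes were added after seeing the data. The matched draws did not keep the number per chromosome. The tests were tested on simulated data. In 60 simulated sets with no effect, 1.56% of gene list p-values were at or under 0.05. The ribosomal protein list with 15 planted peaks was called in 60 of 60 sets. All 20 of 20 hexamers, each planted in 20% of windows, were called. Weaker effects, planted peaks in other lists and a difference in GC content were not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.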

Results

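Binding of GFP-tagged ZAG-1 in L1 larvae was described by 478 peaks on ce11 in the optimal list, drawn from 2 biological replicates. ZAG-1 is known for its part in neuron differentiation and axon development. The optimal peaks were the 478 entries of highest signal in the pooled list of 30000, and the signal ranged from 29.6 to 180 with a median of 38.1. They covered 0.163% of the genome. On ce10 the optimal list held 448 peaks. A −log10 q above 2 was reached by 375 of the 478 peaks, which were all the pooled entries above that value.

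The question for the replicates was whether they ranked the same regions highest. Of the 478 entries ranked highest in replicate 1, 211 (44.1%) overlapped the 478 ranked highest in replicate 2 by 1 bp or more, against a mean of 2.82 in random draws (95% of draws 0 to 6, one-sided permutation p = 1.00e-04, the smallest the draws can give). The overlap fell with depth in the lists, to 36.3% of the 1000 ranked highest (363 against 12.3 in draws) and 22.4% of the 5000 ranked highest (1121 against 304.1). Each of the 20 optimal peaks of highest signal, from cdc-48.1 to Y41G9A.17, overlapped entries among the 478 ranked highest in both replicates. The selection of that list on signal pooled over both replicates favours this. Over the whole optimal list, 280 peaks (58.6%, 95% interval 54.1 to 62.9) overlapped the highest ranked entries of replicate 1 and 365 (76.4%, 72.35 to 79.95) those of replicate 2. Both held 205 peaks (42.9%) and neither held 38 (7.95%). Of the 478 peaks, 467 (97.7%) overlapped any of the 30000 entries of replicate 1, and 478 any of those of replicate 2.

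Across 10068 pairs of overlapping entries, the signal of the replicates had a Spearman's rho of 0.240 (permutation p = 1.00e-05, the smallest possible). Within the 541 pairs at optimal peaks rho was 0.144 (permutation p = 8.00e-04), but some entries occur in more than 1 pair. In pairs whose entries occur in no other pair, added after seeing the data, rho was 0.243 over 8789 pairs and 0.223 over the 432 at optimal peaks. Selection on high pooled signal also alters rho, so these values were not compared. These values are across regions, which are not independent replicates.

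**Figure D1:**
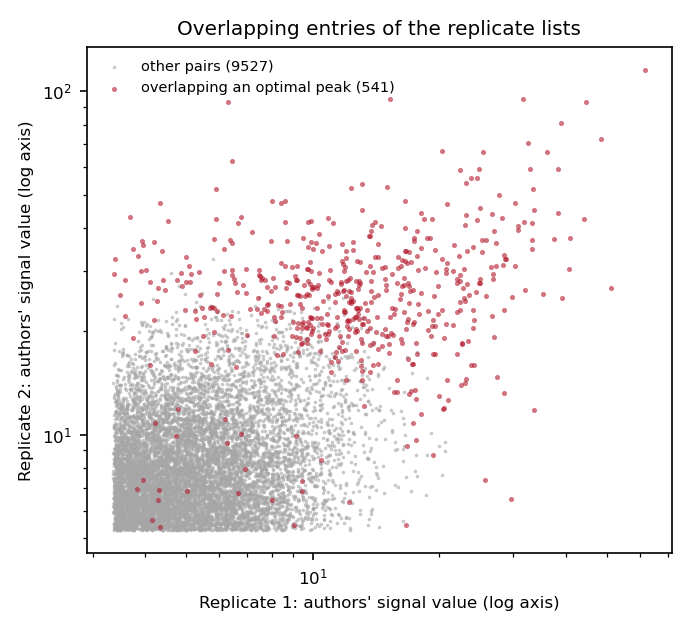
Signal values of the authors for 10068 overlapping entries of the replicate lists, replicate 1 on the horizontal and replicate 2 on the vertical axis, both logarithmic. The 541 pairs at optimal peaks, a list of the entries highest in pooled signal, are in red, and some lie low on 1 or both axes. Over all pairs rho was 0.240.

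The strongest peak lay near cdc-48.1, which encodes an AAA ATPase of protein quality control, at II 10563485 to 10563653 on ce11, with a signal of 180 and its summit in intergenic sequence 155 bp from the annotated start. The next was at IV 11082821 to 11083164, in intergenic sequence 740 bp from the start of let-70, a ubiquitin-conjugating enzyme, with a signal of 140.5. The following 3 were a peak 266 bp from the start of rpl-3, a large-subunit ribosomal protein gene, at III 3867542 to 3867639 with a signal of 123.5, a peak in intergenic sequence 704 bp from ZK1248.17 at II 5844665 to 5845008 with a signal of 121, and a peak 171 bp from ekl-4 at I 14469320 to 14469407. The peaks at cdc-48.1, rpl-3 and ekl-4 were the 3 entries narrower than the fixed width of 344 bp. The other genes among the first 20, in order of signal, were Y17G9B.5, the sphingomyelin synthase gene sms-2, egg-5, nspc-17, the zinc finger gene zfp-1, the vesicle tethering gene vps-51, W02H3.3, dld-1 (dihydrolipoamide dehydrogenase), rpl-15, F01G4.6, ZK899.6, K12H4.5, the homeobox gene ceh-38, tasp-1 and Y41G9A.17. Their signal fell to 76.3 at Y41G9A.17. The peaks at let-70, ZK1248.17 and egg-5 overlapped the small RNA genes M7.15, sls-2.1 and sls-2.4. Of these 20 summits, 10 lay in a TSS window, 8 in intergenic sequence and 2 in introns, at zfp-1 and Y41G9A.17.

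Neither zag-1 nor unc-119, which the transgene may carry too, had an optimal peak within 20 kb. The same was so for 81.8% and 81.7% of windows of those lengths, which held 0.217 and 0.219 optimal peaks on average. Within 20 kb of zag-1 (IV 3855843 to 3861569, plus strand) the optimal list held 0 peaks and the pooled list held 1 entry, where windows of that length held 13.7 pooled entries on average and 0.810% of 20002 windows held as few. Replicate 1 had 2 entries there and replicate 2 had 0. Around unc-119 (III 10902641 to 10908935, plus strand), the pooled list held 18 entries against an average of 13.8, the nearest 0.545 kb from its start, and none was an optimal peak. The optimal peak nearest the start of zag-1 lay 30.9 kb away.

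**Figure D2:**
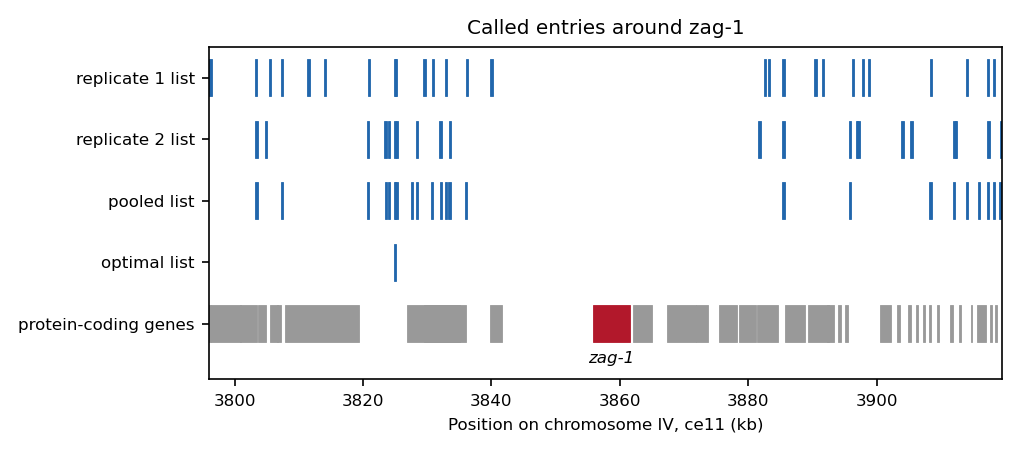
Called entries on chromosome IV around zag-1 (position in kb on ce11). Each row is a list, blue marks are entries, grey blocks are protein-coding genes and the red block is zag-1. No summit of the replicate or pooled lists lay between those at 3840019 and 3881771.

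Optimal summits were concentrated near the starts of genes. In the TSS window lay 241 of 478 summits (50.4%, 95% interval 45.95 to 54.88), against a mean of 25.9% in draws from the pooled list (95% of draws 22.2 to 29.7, permutation adjusted p = 3.00e-04). Outside that window, introns held 14.02% against 28.7%, UTRs 0.837% against 3.55% and coding exons 0 of 478 against 8.92%, each lower with a permutation adjusted p of 3.00e-04. These are shares of all summits, so the larger TSS-window share leaves less room for every other class. Shares among the summits outside the TSS window were not tested. A count of 0 allows a coding exon share of up to 0.797%, but the list of replicate 1 had 6 of 478 summits there (1.26%, 95% interval 0.577 to 2.71), still lower than in draws. Intergenic sequence outside the TSS window held 30.3% against 30.5% (permutation adjusted p = 1.00), and other genes 4.39% against 2.47% (adjusted p = 0.0206). The excess in other genes was not past the threshold in any of the 5 alternatives planned for it. In the upper 239 peaks UTRs held 1.26% against 3.54%, past the threshold no longer (permutation adjusted p = 0.0936). The median distance from a summit to the nearest start was 478 bp in the optimal list and 1222 bp in the pooled list.

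By chromosome, I held 21.8% of peaks (against 15.2% in draws, permutation adjusted p = 0.0012) and III held 91 peaks (19.04% against 14.5%, adjusted p = 0.0124). V held 57, which was lower than in draws (11.9% against 18.97%, permutation adjusted p = 0.0012). X held 84 peaks (17.6% against 19.7%, permutation adjusted p = 0.377), and II and IV held 59 and 83 (adjusted p = 0.758 and 0.626). In the upper 239 peaks and in the list of replicate 1, the calls for chromosome I (permutation adjusted p = 0.291 and 0.237) and III (adjusted p = 0.107 and 0.0750) were lost. That for III was lost on ce10 too (permutation adjusted p = 0.102).

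Among the 16 gene lists, ribosomal protein genes and pan-neuronal genes had more members with a peak than draws from the pooled list. Of the 478 peaks, 454 were assigned to 435 genes. Ribosomal protein genes had 17 of 81 members with a peak, against a mean of 1.49 (95% of draws 0 to 4, permutation adjusted p = 0.0016). All 17 had the peak in a TSS window, led by rpl-3, rpl-15 (signal 85.15), rpl-11.2 (73.4) and rpl-12 (72.1). Pan-neuronal synaptic and vesicle genes had 13 of 39 members with a peak, against a mean of 2.92 (95% of draws 0 to 6, permutation adjusted p = 0.0016). They were led by unc-108, a Rab GTPase gene (signal 68.2), unc-76 (67.5), the ankyrin gene unc-44 (54.1) and egl-3, a proprotein convertase gene for neuropeptides (49.9), and 5 of the 13 peaks lay in a TSS window. With draws matched on GC content and the TSS window, added after seeing the data, the ratio of observed to mean count fell from 11.4 to 4.30 for ribosomal protein genes (permutation adjusted p = 0.0032) and from 4.46 to 2.42 for pan-neuronal genes (adjusted p = 0.0256). Those draws could take optimal peaks again, which raises their mean, so part of the fall may be built in. Unlike the main draws, they did not keep the number of peaks per chromosome.

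The other neuronal lists had no excess past the threshold. Neuron identity transcription factors had 0 of 58 members with a peak against a mean of 2.56 (permutation adjusted p = 0.743), where the 95% of draws from 0 to 6 left no room for a deficit. In the list of replicate 1 the count was 2 against 2.41. Neurotransmitter synthesis and transport genes had 0 of 20 against 0.431 and touch receptor neuron genes 0 of 15 against 0.615. Neuronal receptors and ion channels had 2 of 78 against 4.24, the innexin gene unc-9 (signal 54.04) and unc-80 (37.3). Neuropeptide genes had 3 of 144 against 4.11, ins-13 (73.5), ins-39 (39.4) and nlp-40 (39.2). Axon guidance and cell migration genes had 2 of 60 against 3.44, the netrin receptor gene unc-40 (35.98) and lin-18 (34.2). Each of these 5 lists had an adjusted p of 1. The peak named for ins-13 overlapped the small nuclear RNA gene sls-2.2 and lay 1307 bp from the start of ins-13.

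Lists for other tissues and housekeeping complexes had none either. Body wall muscle genes had 0 of 42 members with a peak against 1.97, and intestine genes 0 of 91 against 0.958. Epidermis and cuticle genes had 2 of 209 against 2.86, col-94 (signal 52.3, a peak that overlapped the small nuclear RNA gene R07E5.16) and col-185 (41.4). Germline genes had 2 of 88 against 1.085, puf-9 (44.5) and the Polycomb gene mes-2 (36.2). Cadherin, junction and polarity genes had 1 of 25 against 1.82 (zoo-1, 35.97), pharynx genes 1 of 26 against 0.442 (ceh-22, 29.9), proteasome genes 1 of 33 against 0.404 (rpn-3, 42.6) and histone genes 1 of 72 against 0.283 (his-37, 65.99). The adjusted p was 1 for each of these 8 lists. Among the lists without an excess, only neuronal receptors and neuropeptides had 95% of draws that started above 0 (1 to 8 for both), so a deficit could not be shown for any other, body wall muscle genes included. A gene assigned no pooled entry could not be counted in any list. Pooled entries were assigned to 10 of 72 histone, 35 of 88 germline and 41 of 91 intestine genes, but to 38 of 42 body wall muscle genes.

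**Figure D3:**
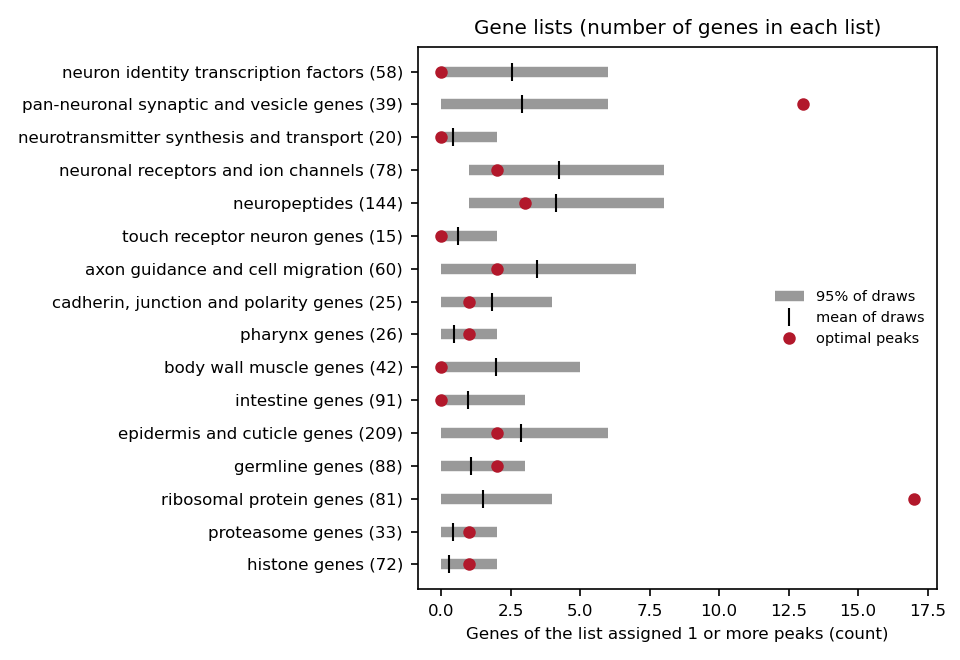
Number of genes of each of 16 lists assigned 1 or more optimal peaks (red points), with the mean (black ticks) and 95% range (grey bars) of 10000 draws from the pooled list. Ribosomal protein genes (17) and pan-neuronal genes (13) lie outside their ranges of 0 to 4 and 0 to 6.

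The E-box CAGGTR, the site known for ZEB-class proteins, was less frequent at optimal summits than at other pooled entries. It occurred in 17 of 478 windows (3.56%, 95% interval 2.23 to 5.62) against 7.998% of 29444 (7.69 to 8.31), an odds ratio of 0.424 (95% interval 0.270 to 0.704, Fisher's exact test, adjusted p = 2.49e-04). CAGGTG alone was at 1.88% against 3.93% (Fisher's exact test, adjusted p = 0.0266), a call lost in 5 of 8 alternatives, and CAGGTA was at 1.67% against 4.28%, a call lost among TSS-window peaks. With windows of 50 bp on each side the odds ratio was 0.515 and its adjusted p was 0.0512, past the threshold no longer. Peaks with CAGGTR had a median signal rank of 274 against 238 without it, a difference of 36 ranks that was within chance (permutation p = 0.544).

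Among the 11 motifs, the largest odds ratio was that of GAGAGA, in 236 of 478 windows (49.4%, 95% interval 44.9 to 53.8) against 12.3%, an odds ratio of 6.97 (95% interval 5.80 to 8.36, Fisher's exact test, adjusted p = 8.61e-84). CAGCTG was at 5.02% against 3.20% (Fisher's exact test, adjusted p = 0.0486). That call was kept with windows of 50 and 250 bp. It was lost in the upper 239 peaks, against flanks, in the list of either replicate alone and among TSS-window peaks. The GATA-type motif HGATAR (33.5% against 44.2%), the homeodomain core TAATTA (4.81% against 11.4%) and TTTTTTTT (15.1% against 28.5%) were less frequent. CACGTG, CATATG and CAGATG missed the threshold (Fisher's exact test, adjusted p = 0.336, 0.207 and 0.720). Windows at optimal summits had a mean GC content of 43.25%, against 32.9% in the background. Against GC-matched entries, whose mean GC content was 41.7%, the odds ratio was 2.93 for GAGAGA and 0.333 for CAGGTR, and the calls for CAGCTG, HGATAR, TAATTA and TTTTTTTT were lost. HGATAR was still less frequent, with an odds ratio of 0.796 (0.653 to 0.974, Fisher's exact test, adjusted p = 0.0553), and TAATTA had one of 0.821 (0.541 to 1.29).

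Of 2080 hexamers, 1108 differed in frequency, 652 higher and 456 lower at optimal peaks. The leading ones were CGTCTC (36.4% against 5.72%), GAGAGA, AGAGAG (43.5% against 10.1%), AGAGAC (37.45% against 7.63%) and GACGCA (27.8% against 4.26%). These share sequence and are not separate motifs. GACGCA and GAGACG, the reverse complement of CGTCTC, both lie within GAGACGCAGA. That longer word, not among the tests fixed in advance, was in 14.4% of optimal windows, against 1.18% of the background and 4.44% of GC-matched entries. CAGGTA ranked 851 and CACCTG, the reverse complement of CAGGTG, ranked 1051 by p. Against GC-matched entries, 405 hexamers differed, 189 higher and 216 lower, and GAGAGA and CGTCTC ranked first and second. There CACCTG ranked 139 (1.88% against 5.77%) and CAGGTA ranked 253 (1.67% against 4.58%), both less frequent at optimal peaks.

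**Figure D4:**
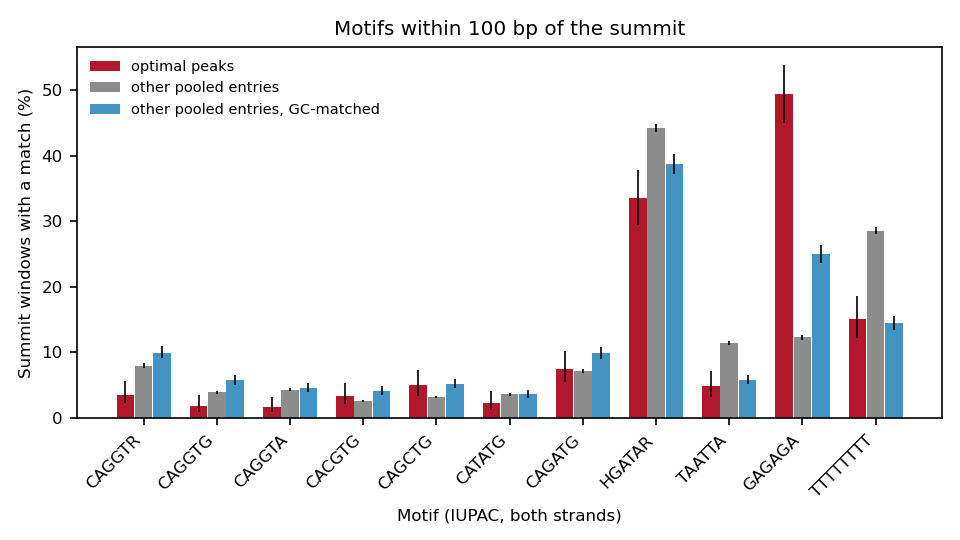
Share of summit windows with each of 11 motifs (percent, vertical axis) at optimal peaks (red), other pooled entries (grey) and GC-matched pooled entries (blue), with 95% Wilson intervals. GAGAGA was at 49.4% at optimal peaks against 12.3% and 24.98%, and CAGGTR at 3.56% against 7.998% and 9.96%.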

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

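Alternatives with narrower peaks removed, with pairs of entries used once, with matched draws or with TSS-window peaks alone were chosen after seeing the data. The replicate overlap, the rank correlation, the TSS-window share and the share on X kept their direction and side of the threshold in all alternatives run. The ribosomal protein ratio ranged from 4.08 to 18.3 and the pan-neuronal ratio from 2.14 to 9.90 over 11 alternatives, all past the threshold (highest adjusted p 0.0032 and 0.0464). The CAGGTR odds ratio stayed under 1 (0.269 to 0.523 without a replicate), and lost its call with windows of 50 bp (0.515), where 10 peaks held a match. The upper list held 239 peaks, by construction. Against GC-matched entries 405 hexamers were called, and 1108 against all others.

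Direction changed in 34 results. In 29 neither value was past its threshold, in 4 the reported value was and in 1 the alternative was; the cause was not tested. Ratios of observed to mean follow. For the upper 239 peaks they were 1.44 for neuropeptides, 0 for pharynx genes, 1.40 for epidermis and cuticle genes and 1.08 for chromosome IV. With assignment within 1000 bp they were 1.55 for axon guidance, 1.46 for cell junctions and 0 for pharynx genes. Fisher's exact test on genes gave 1.015 for axon guidance and 1.45 for cell junctions. Matched draws gave 1.20 for neuropeptides and 0.870 for histones, and 1.45 for neuropeptides with GAGAGA matched too. Intergenic summits were at 1.19 against random positions and 1.00 without the narrower peaks.

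Without a replicate the ranges were 1.58 to 1.75 for touch receptor genes, 0.741 to 1.98 for germline genes, 0.692 to 1.05 for receptors and channels, 0 to 2.13 for pharynx genes, 0.980 to 1.07 for intergenic summits, 0.959 to 1.44 for other genes and 0.993 to 1.00 for chromosome IV. Motif odds ratios ranged from 0.999 to 1.46 for CAGCTG, 0.686 to 1.02 for CATATG and 0.805 to 0.868 for CAGATG. CAGATG was at 0.935 in the upper 239 peaks, 0.902 within 50 bp, 0.742 with GC matching and 0.971 against flanks. CACGTG was at 0.797 with GC matching and 0.837 against flanks. With GC matching CAGCTG was at 0.963 and TTTTTTTT at 1.05. The number of reads was not used here, so what depth limits was not measured.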

Other observations

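The overlap with non-coding genes, the motif shares along the ranked pooled list and the tests of CAGGTR binding, of chance spacing and of copies in the control were chosen after the results were seen. Matched draws for gene lists and motifs among peaks near starts were added after seeing the data. Non-coding genes differed by class among the 10 classes tested. Small nuclear RNA genes lay under 9 optimal peaks, against a mean of 0.441 in draws from the pooled list (95% of draws 0 to 2, permutation adjusted p = 6.67e-04). Some of these peaks overlap one another, and the 9 make 7 separate regions. Of them, 6, in 4 separate regions, lay over 4 of the 18 annotated sls-2 genes, which encode spliced leader RNAs used in trans-splicing. The sls-2.1 gene lay under the peak of rank 4 and sls-2.4 under that of rank 8. Transfer RNA genes lay under 8 peaks against 2.57 (permutation adjusted p = 0.0230) and small nucleolar RNA genes under 5 against 1.34 (adjusted p = 0.0397). Genes annotated as ncRNA lay under 85 peaks against 19.2 (permutation adjusted p = 6.67e-04). Piwi-interacting RNA genes were under 1 peak against 21.4 (permutation adjusted p = 6.67e-04), and pseudogenes under 3 against 9.60 (adjusted p = 0.0397). No draws matched on GC content or the TSS window were made for these classes, so what those features contribute was not tested.

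Along the pooled list, ranked by signal, GAGAGA fell from 49.4% of the first 478 entries to 9.90% of those ranked 20001 to 30000, while CAGGTR rose from 3.56% to 8.79%. Mean GC content fell from 43.25% to 32.7% and the TSS-window share from 50.4% to 23.9% over the same ranks, so the effects were not separated.

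Optimal peaks held few CAGGTR sites and many GAGAGA sites, and GC content, position near starts and direct binding at CAGGTR were weighed. GC content as the whole cause was argued against by the GAGAGA odds ratio of 2.93 (95% interval 2.415 to 3.55) against GC-matched entries, although the mean GC content still differed, 43.25% against 41.7%. Position near starts as the whole cause was argued against by an odds ratio of 3.455 among peaks within 500 bp of a start (2.64 to 4.54). GC content was not matched there, at 42.2% against 33.7%. The 2 were not matched together for motifs, so their joint effect was not tested. Those odds ratios concern GAGAGA, and for CAGGTR they were 0.333 (0.210 to 0.558) against GC-matched entries and 0.501 (0.287 to 0.949) near starts. Direct binding at CAGGTR in most peaks was argued against by its share of 3.56% (2.23 to 5.62). Recruitment through other proteins or open chromatin may account for the rest, and neither was tested, since no peaks of other factors were used here.

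Ribosomal protein and pan-neuronal genes were over-represented, and their GC content, TSS position and GAGA-rich sequence were weighed. With draws matched on GC content and the TSS window, the observed count was 4.30 times the mean for ribosomal protein genes (95% of draws 0.253 to 2.02) and 2.42 times for pan-neuronal genes (0.372 to 1.86). Matching on GAGAGA as well gave 4.08 (0.240 to 1.92) and 2.14 (0.329 to 1.81). GC content and the TSS window, matched together, may explain part of the excess, since the ratios fell from 11.4 and 4.46. Part of that fall may be built in, because the matched draws could take optimal peaks again. Matched in this way, these features did not account for the whole excess. GC content was matched only in bins, and position only as inside or outside the TSS window. The GC difference left within bins is not given, so finer differences in either feature were not excluded as the whole cause. Their shares were not separated. No biological explanation was tested.

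The stretch of 41.75 kb around zag-1 between the summits at IV 3840019 and 3881771 contained 6 whole protein-coding genes and no summit of the 3 lists. Chance spacing was argued against by the 0.235% of 20008 intervals of that length that held no entry. The stretch was not the longest, and ranked 5 by length among 86827 gaps between summits of the 3 lists together. That length came from the stretch itself. The window of 20 kb around zag-1, a gene named before the data were examined, was as sparse in 0.810% of windows. That comparison was not among the tests fixed in advance. The GC content of the stretch was at percentile 96.8 and its masked share at percentile 30.9, both inside the middle 95%, the first narrowly, and of 517 intervals alike in both 0% were empty. Extra copies of the region in the control library, if it came from the same transgenic strain, may remove entries, and cannot be told apart from other causes here because control coverage was not used; the 18 pooled entries within 20 kb of unc-119, of which the transgene may carry a shorter stretch, do not decide it.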
